A study of Mus musculus with 6 samples.

How the data were processed

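Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in organoids grown from the small-intestinal epithelium of C57BL/6JRj mice. Organoids are self-organising epithelial cultures that hold stem cells and their differentiated progeny. Per the labels, 3 libraries came from mice aged 2 to 3 months (young) and 3 from mice aged 20 to 22 months (aged). The cultures were kept for 3 to 5 weeks and harvested at passage 4 (replicate 1), 3 (replicate 2) or 2 (replicate 3), with 1 young and 1 aged library at each passage. Per the labels' protocols, organoids were dissociated to single cells, treated with Tn5 and amplified with 20 PCR cycles. Neither the titles nor the protocols say that the 3 libraries of an age came from separate animals, and the culture codes in the titles differ from those in the descriptions, so p-values measure only the spread between these samples. In the titles, same-numbered young and aged libraries share a culture code and a passage, so the numbers were taken to pair them. Deviations from the group means correlated only slightly within these pairs (r = 0.074, 0.127 and 0.144), although each library correlated best with its own number. The fit fixed beforehand had no block, and values with the replicate number as a block are given where they change a call or move a count of calls by over 1.5 times.

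The deposited files are a table of counts per consensus peak, with 1 column per library, and an annotation of the same 156733 peaks on GRCm38. Per the submitters' processing notes, the authors used FastQC 0.11.9, Trim Galore 0.6.4, BWA 0.7.17-r1188, SAMtools 1.10, Picard 2.23.1, bedtools 2.29.2, deepTools 3.4.3, MACS2 2.2.7.1, featureCounts 2.0.1, MultiQC 1.9 and R 3.6.2. Per the file headers, the counts came from featureCounts over the consensus peaks and were not normalised. Whether fragments or reads were counted, whether reads were shifted for the Tn5 offset and how duplicates were treated is not given in the sources used here. The reads carry no molecular identifiers, so the precision of a count covers counting error only. The deposited annotation gives each peak a class (promoter-TSS, exon, intron, TTS for transcription termination site, or intergenic) and the gene with the nearest transcription start site (TSS), which is the gene named for a peak unless the peak is said to lie in another gene, by the annotation or the RefSeq span. The start positions of the files differ by 1 bp, and the 1-based ones are printed. The score column of the annotation was not used. Gene names were matched to a RefSeq table of GRCm38.p6, in which 24413 of 31309 names were found.

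Aged was compared with young in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with robust dispersion estimation, TMM factors and the filterByExpr filter (minimum count 10), which kept 132055 peaks and left out 24678. Peaks were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 fold changes are aged over young. Values per library are CPM, computed here from the deposited counts with TMM-scaled library sizes. The passage trend was tested as a numeric term beside age. The camera test of limma 3.58.1 was applied to log2 CPM with a prior count of 2 and a correlation preset at 0.01, and again with an estimated correlation. The fry test was run beside it. Its directional p tests whether the peaks of a set move, on balance, one way, its mixed p whether they change in either direction, and neither compares the set with other peaks. Library totals and composition were compared by exact permutation tests, two-sided. Shares of called peaks per class were compared by Fisher's exact test, two-sided, in which neighbouring peaks are not independent replicates.

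Before the data were examined, the tests, the processing alternatives other than those said below to be added, the rule for named peaks and 22 gene lists were fixed. The lists were MHC class II, MHC class I and antigen processing, interferon response, NF-kB and inflammation, AP-1 and immediate early genes, intestinal stem cell, Wnt and Notch pathway, proliferation, enterocyte, goblet, Paneth, enteroendocrine, tuft, epithelial identity transcription factors, distal intestine and colon, regenerative and fetal-like epithelium, senescence and p53 response, antimicrobial lectins and peptides, immune cells, stromal cells, endothelial and neural cells, and housekeeping. All 349 list genes were found in the RefSeq table, and 330 had an annotated peak. At promoters, each gene was represented by the peak within 1 kb of its TSS with the most counts, and a wider test took all peaks within 50 kb. The rule for named peaks took the 10 higher and 10 lower called peaks with the largest fold changes that had the same sign in all 3 same-numbered pairs and lay within 50 kb of the TSS, 1 per gene. It also named the 3 smallest p-values per list at promoters and 10 genes fixed by name.

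Alternatives were RLE factors, library totals alone, abundance-trended loess offsets (span 0.3), no filter, a stricter filter (30 counts in 3 libraries), a replicate block, no X or Y peaks, each library left out in turn, DESeq2 1.42.0, limma-voom, non-robust dispersions and an adjusted p under 0.1. Gene lists were also tested with a promoter window of 3 kb, the peak nearest to the TSS and a distance of 10 kb. Thinning all libraries to the total of young replicate 1, the test of an age by passage interaction, the sign-flip test over same-numbered pairs, the comparison of promoter shares, the protein-coding promoters, the runs of neighbouring calls and the homeobox, imprinted and zinc finger lists were added after seeing the data. The motif sets and the alternatives with GC correction were not run, because no genome sequence was used here. The scripts were tested on simulated data made from the real means and library sizes over 132055 peaks. With 50 peaks changed at each size, the aged against young test recovered 30% (15 peaks) at a log2 fold change of 0.5. It recovered 56% (28) at 1, 86% (43) at 2 and 94% (47) at 3. It also called 15 of 129525 unchanged peaks. Beside the recovered peaks these false calls were not few, and their share among the calls may have exceeded the adjusted p threshold used. With no peak changed it called 3 of 129706, all of them false. In the simulated lists, of 25 independent peaks each, camera called 4 of 4 that were shifted by 0.5 and 0 of 18 that were not. The real promoter lists held 2 to 29 peaks and real peaks can move together, so these rates need not hold for them. Of 200 simulated peaks with a log2 slope of 1 per passage, 85% were recovered. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.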

Results

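The study asked how chromatin accessibility of the small-intestinal epithelium differs between aged and young mice once the cells have been grown as organoids. It comprised 6 ATAC-seq libraries, 3 young and 3 aged, counted over 156733 consensus peaks. The young libraries held 7278161, 25901670 and 19208483 counts in peaks (replicates 1 to 3) and the aged libraries 22363682, 21687816 and 26093521. Young replicate 1 was the shallowest, with 5283 peaks at a count of 0 against 123 to 718 in the others. On the first principal component of log2 CPM, which held 37.6% of the variance, young replicate 1 lay apart from the other libraries. Young replicate 3 lay apart on the second, which held 22.3%. No pair of libraries agreed within counting noise: chi-square per degree of freedom was 1.72 to 3.61. Correlations between libraries (across peaks, which are not independent replicates) were 0.955 to 0.972 among the young, 0.976 to 0.979 among the aged and 0.951 to 0.975 between the ages.

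**Figure D1:**
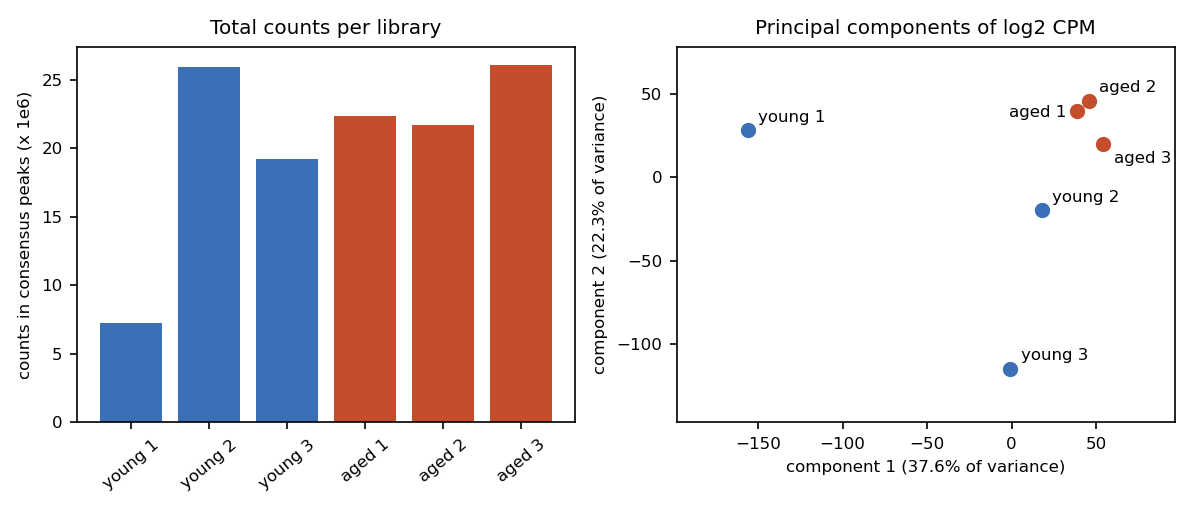
Left, total counts in consensus peaks per library, young in blue and aged in orange; young replicate 1 had 7278161 and the others 19208483 to 26093521. Right, the libraries on principal components 1 (37.6% of the variance) and 2 (22.3%) of log2 CPM.

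Total signal and its distribution over peaks passed no test between the ages. Promoter peaks took 30.93% ± 0.70 (SD, n = 3) of counts in young and 31.60% ± 0.20 (SD, n = 3) in aged libraries (exact permutation p = 0.3, two-sided), with single young libraries at 31.05, 31.56 and 30.19%. Chromosome X took 1.405% ± 0.0085 in young and 1.38% ± 0.025 in aged libraries (exact permutation p = 0.2). The 1% of peaks with most counts took 12.46% and 12.66% (exact permutation p = 0.6), total counts gave p = 0.4 and the share of chromosome Y counts p = 0.4 by the same exact test. Over these 5 exact tests Benjamini-Hochberg adjusted values were 0.5 to 0.6, and 3 libraries against 3 cannot go below p = 0.1. Within the same-numbered pairs the promoter share rose in 3 of 3 (31.05 to 31.44%, 31.56 to 31.83% and 30.19 to 31.54%) and the chromosome X share fell in 3 of 3 (1.395 to 1.393%, 1.407 to 1.396% and 1.411 to 1.351%). An exact sign-flip test over 3 pairs, added after the data were seen, gave p = 0.25 for each, the smallest it can give (BH-adjusted 0.5 over the 5 measures).

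Aged and young organoids differed strongly at a small set of peaks. Intronic peaks of Iscu, a scaffold protein of mitochondrial iron-sulfur cluster assembly, and of Tspan12, a tetraspanin co-receptor of Norrin and Frizzled signalling, rose in aged organoids. Peaks in Lrrc8b, a subunit of volume-regulated anion channels, and near Isyna1, the enzyme that starts inositol synthesis, fell, as did a group of intronic peaks of Tiam1, an activator of the GTPase Rac. A promoter peak of Pcbp3, an RNA-binding protein, fell as well. Many of the other largest changes had a pseudogene or noncoding transcript as the nearest TSS, often over 10 kb away. Of 132055 peaks tested, edgeR's quasi-likelihood test called 1491 (1.13%), 818 higher and 673 lower in aged, and 12822 had an unadjusted p under 0.05. The median absolute log2 fold change of the called peaks was 1.11 (quartiles 0.80 and 1.52), and 449 rose and 426 fell by 2-fold or more. The called peaks were nearest to 1291 genes. Without aged replicate 3 the count was 830 (452 higher, 378 lower), of which 786 were among the 1491, and DESeq2 called 901, of which 900 were among them. With the replicate block edgeR called 3523 (1930 higher, 1593 lower), among them all 1491.

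Among the 20 peaks taken by the rule on size, the intron 3 peak of Iscu (chromosome 5, 113776574 to 113776883) went from 0.742 ± 0.089 CPM in young to 5.56 ± 2.06 in aged (SD, n = 3; log2 fold change 2.90, SE 0.27; edgeR adjusted p = 2.7e-08). The intron 2 peak of Tspan12 (chromosome 6, 21843855 to 21844022) went from 0.190 ± 0.168 to 1.79 ± 0.015 CPM (log2 2.96, SE 0.40; adjusted p = 1.4e-05). In the opposite direction, the intron 1 peak of Lrrc8b (chromosome 5, 105418245 to 105418448) went from 4.81 ± 1.16 to 0.471 ± 0.272 CPM (log2 -3.42, SE 0.28; adjusted p = 9.1e-10). The Isyna1 peak (chromosome 8, 70598437 to 70598592), 4.03 kb from its TSS and inside an intron of another gene, went from 4.24 ± 1.31 to 0.414 ± 0.245 CPM (log2 -3.36, SE 0.31; adjusted p = 1.9e-08). The smallest adjusted p of all tested peaks, 3.3e-16, belonged to a peak on chromosome 10 (76961743 to 76962452) annotated as a promoter of Pcbp3, although the nearest TSS in the annotation, 21.8 kb away, was that of Gm37782. It went from 20.0 ± 1.21 to 1.86 ± 0.287 CPM (log2 -3.42, SE 0.16). The most abundant of the higher peaks was intergenic, 34.4 kb from the pseudogene Gm17177, and went from 2.13 ± 0.995 to 16.4 ± 1.80 CPM (log2 2.81), and the noncoding Gm16046 promoter went from 15.6 ± 4.37 to 1.45 ± 0.158 CPM (log2 -3.39).

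The other named peaks are given by the nearest TSS, mostly of noncoding genes and pseudogenes, which does not tie a peak to that gene. Higher in aged were promoter peaks of RP23-192C21.3 (log2 2.77) and Gm7592 (2.75), a peak in a TTS of St3gal2 (3.11, 17.4 kb from Gm26816) and intergenic peaks 15.2 kb from Gm15270 (3.10) and 30 kb from Gm38357 (2.67). Lower were promoter peaks of 9030624G23Rik (-3.36) and Gm17391 (-3.29), and a peak of the promoter-TSS class inside Elavl2 and 1.31 kb from Mir6402 (-3.50). Also lower were intergenic peaks 2.12 kb from Gm5633 (-3.27) and 3.81 kb from C230035I16Rik (-3.15). The peaks named 9030624G23Rik, Gm17391 and Gm5633 lie in a stretch of chromosome 12 with many gene copies, between which reads can be shared. Some folds of higher peaks rest on few young counts, among them those of Tspan12 (1, 10 and 1), RP23-192C21.3 (1, 7 and 1) and Gm7592 (1, 4 and 2). For 3 further peaks 1 group held almost no counts, so counts are given in place of folds. The intergenic peak 13.1 kb from Gm18359 (chromosome 7, 85490050 to 85490144) had 0, 1 and 1 counts in young and 13, 12 and 13 in aged libraries. The peak in an intron of Rbpj and 19.3 kb from RP23-137N6.2 (chromosome 5, 53566597 to 53566702) had 0, 3 and 0 against 15, 13 and 18. The intronic peak 25.4 kb from RP23-125B15.1 (chromosome 5, 50654225 to 50654471) had 9, 14 and 20 in young and 0, 3 and 0 in aged libraries. The Gm18359 call was lost without young replicate 2 (edgeR adjusted p = 0.0614) and aged replicate 1 (0.0513, range over the processing alternatives 0.0018 to 0.0614), and the RP23-137N6.2 call without young replicate 3 (0.0564, range 7.0e-04 to 0.0564). The other 18 of the 20 kept their call in each of the 6 fits, and of these the Tspan12 call was lost when all libraries were thinned to young replicate 1 (0.0588, range 3.7e-09 to 0.0588).

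**Figure D2:**
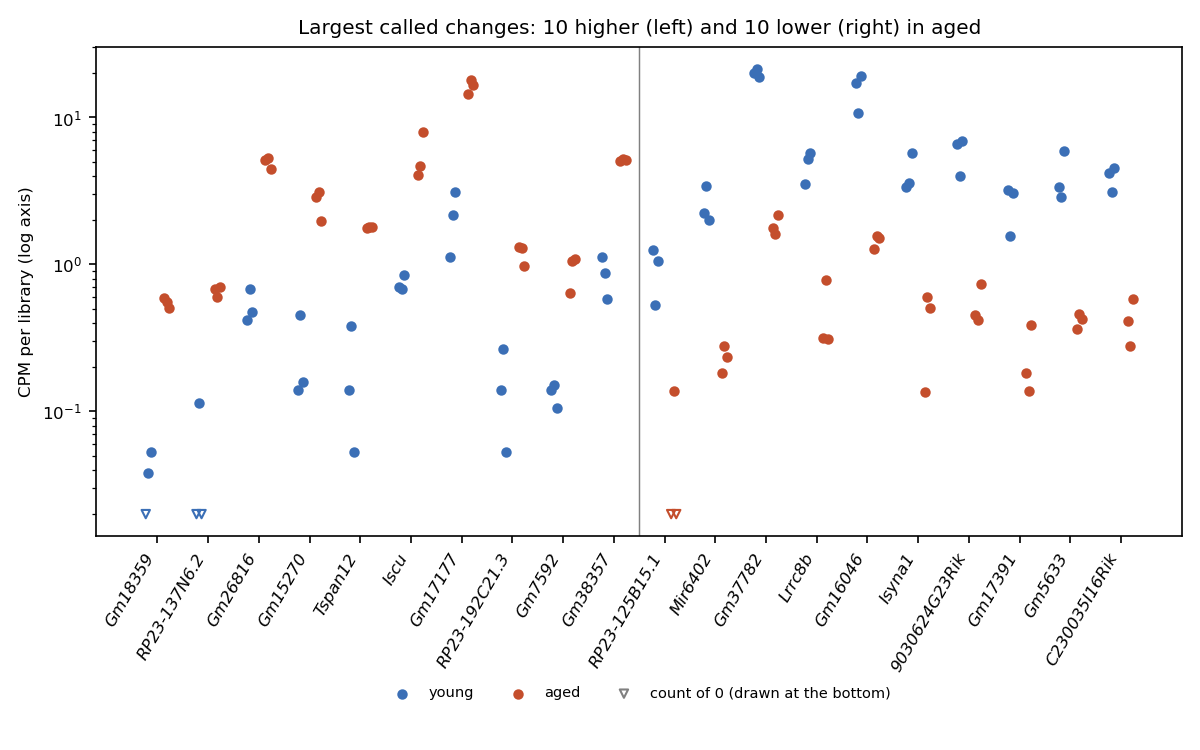
CPM per library (log axis) at the 10 higher (left) and 10 lower (right) peaks with the largest called changes, young in blue and aged in orange, with open triangles for counts of 0 and each peak named by its nearest TSS. At Iscu the aged mean was 5.56 CPM against 0.742 in young, and at the peak named Gm37782 it was 1.86 against 20.0.

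Called promoter peaks of protein-coding genes were mostly weakly open ones. The promoter peaks of Phyhipl, of the glypicans Gpc2 and Gpc3 (cell-surface heparan sulfate proteoglycans), of the netrin receptor Unc5d, of the calcium buffer Calb2 and of the transcription factors Hoxd1, Alx1 and Zic1 fell in aged organoids. Promoter peaks that rose included those of Amhr2, the receptor of anti-Müllerian hormone, Gstp2, a glutathione transferase, Thbs3, a thrombospondin, the secretoglobins Scgb2b18 and Scgb2b20, and Dhx58, a sensor of viral RNA. Within 1 kb of the TSS, edgeR called 42 peaks at 41 protein-coding genes higher and 105 peaks at 102 such genes lower. This balance depended on the fit: of promoter-TSS peaks of all genes, 89 were called higher and 145 lower as designed, but 335 higher and 250 lower with the replicate block, and 273 higher and 117 lower without young replicate 2. These genes were chosen after their values were seen. Every example kept its call with any 1 library left out, but those of Alx1 (edgeR adjusted p = 0.0997, range over the processing alternatives 7.1e-08 to 0.0997) and Zic1 (0.226, range 1.7e-06 to 0.226) were lost when all libraries were thinned to young replicate 1. Of the 146 such peaks other than 9030624G23Rik, 69 kept the call in all 6 of these fits and 77 lost it in at least 1, and 53 kept it under every alternative. The lower peaks had a median of 1.93 CPM, the higher ones 7.21 and those not called 17.3.

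The Phyhipl promoter (chromosome 10, 70598553 to 70600202) went from 15.2 ± 2.06 to 3.85 ± 0.473 CPM (SD, n = 3; log2 -1.98, edgeR adjusted p = 1.8e-10) and the Gpc2 promoter (chromosome 5, 138279715 to 138280477) from 40.8 ± 4.60 to 19.5 ± 0.519 CPM (log2 -1.07, adjusted p = 5.6e-09). The Gpc3 promoter (chromosome X, 52613433 to 52614322) went from 7.77 ± 0.616 to 2.12 ± 0.190 CPM (log2 -1.87, adjusted p = 1.7e-08). Amhr2 (chromosome 15, 102451860 to 102452472) went from 1.96 ± 0.195 to 7.58 ± 0.906 CPM (log2 1.97, adjusted p = 1.9e-08) and Gstp2 (chromosome 19, 4042135 to 4042476) from 11.3 ± 0.174 to 23.3 ± 2.09 CPM (log2 1.04, adjusted p = 2.3e-07). Log2 fold changes of the others were -1.94 for Unc5d, -2.51 for Calb2, -1.72 for Hoxd1, -2.05 for Alx1, -1.73 for Zic1, 1.82 for Thbs3, 1.73 for Scgb2b18, 0.87 for Scgb2b20 and 1.30 for Dhx58. The promoter of Hspa1a, an inducible heat-shock protein, fell by 0.61 (adjusted p = 0.0028).

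Called peaks clustered at single loci, described here after their values were seen. In the Tiam1 region on chromosome 16 (89773744 to 89975953), 6 of 13 tested peaks fell and none rose, with log2 fold changes of -1.08 to -5.39, and each kept its call with any 1 library left out. In the thinned libraries 2 of the 6 calls were lost, those of the largest change (edgeR adjusted p = 0.0570, range 3.1e-55 to 0.0570) and the smallest (0.0598, range 9.3e-05 to 0.0598). The deepest, in intron 1 of Tiam1 (89962818 to 89963305) and 168 kb from the nearest TSS in the annotation, went from 27.8 ± 9.89 to 0.644 ± 0.126 CPM (SD, n = 3; edgeR adjusted p = 3.9e-05). At the Hoxd cluster of homeobox transcription factors on chromosome 2 (74655564 to 74763399), 8 of 25 tested peaks were called, and the higher calls lay between lower ones. Peaks of Evx2 (log2 -1.51 and -1.14), Hoxd11 (-1.50), Hoxd9 (-1.01) and Hoxd1 (-1.72) fell, and 3 peaks nearest to Mir10b (1.06, 0.95 and 0.91) rose. The first Evx2 peak, the Hoxd1 peak and the first Mir10b peak kept their calls with any 1 library left out, and that Mir10b call was lost in the thinned libraries (0.263, range 2.9e-05 to 0.263). Without young replicate 2 the calls of Hoxd11 (edgeR adjusted p = 0.0754, range over the processing alternatives 2.8e-06 to 0.0815), Hoxd9 (0.102) and the other Mir10b peaks (0.242, and 0.103 with a range of 3.0e-04 to 0.1496) were lost. The Hoxd9 call was also lost without aged replicate 2 (0.0817) and aged replicate 3 (0.0880, range 3.2e-04 to 0.1702), and that of the second Mir10b peak without aged replicates 1 (0.109) and 3 (0.159, range 9.6e-04 to 0.282). The second Evx2 call was lost without each library in turn (young replicates 1 to 3 0.0895, 0.167 and 0.0546, aged replicates 1 to 3 0.0783, 0.0630 and 0.328, range 0.0115 to 0.328).

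**Figure D3:**
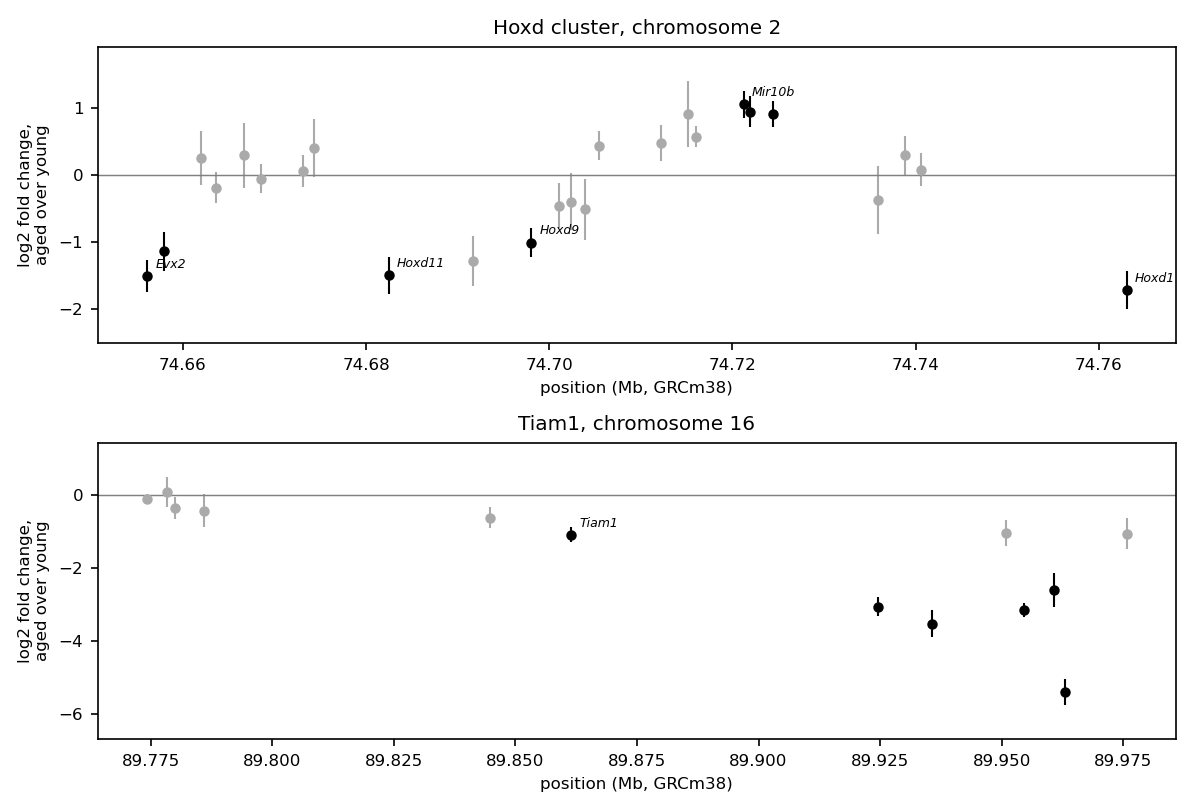
Log2 fold change, aged over young (points, with SE as bars), of tested peaks along the Hoxd cluster and the Tiam1 region (position in Mb, GRCm38), called peaks in black and others in grey. In the Tiam1 region 6 of 13 peaks fell, and along Hoxd 5 fell and 3 rose.

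By genomic class, in the fit as designed, promoter-TSS and exon peaks made up more of the peaks that fell than of those that rose, and intron peaks less. Promoter-TSS peaks were 145 of the lower peaks (21.6%) and 89 of the higher ones (10.9%), an odds ratio of 2.25 (95% interval 1.67 to 3.03; Fisher's exact test, BH-adjusted p = 9.9e-08 over 5 classes). Exon peaks were 12.04% and 7.09% (odds ratio 1.79, adjusted p = 0.0021) and intron peaks 29.0% and 38.1% (0.662, adjusted p = 5.7e-04). The shares of intergenic (adjusted p = 0.058) and TTS peaks (0.18) did not pass the test. These Fisher tests take peaks as units, so their p-values do not cover the spread between libraries. The exon and intron splits were not refitted under the alternatives. The promoter split over all calls depended on the fit. With the replicate block promoter-TSS peaks were 15.7% of the lower and 17.4% of the higher calls (Fisher's exact p = 0.188), with 246 higher (median log2 0.36) and 105 lower (-0.66) promoter calls added. The split reversed without young replicate 2: promoter-TSS peaks were then 13.9% of the lower and 25.7% of the higher calls, because 206 small higher promoter calls were added (median log2 0.46). Among calls of 2-fold or more it kept its direction, with promoter-TSS peaks at 25.8% of the lower and 8.24% of the higher calls in all libraries, 18.8% and 9.61% without young replicate 2, and 22.0% and 7.81% with the replicate block. Most of the added higher promoter calls lie under that cut, so the kept direction was largely set by it. Over all peaks of a class, camera called 0 of 5 classes, with 1 class under an unadjusted p of 0.05. That class was promoter-TSS (direction up, p = 0.034, adjusted 0.168, adjusted p = 0.451 with an estimated correlation), whose median log2 fold change over all its tested peaks was 0.03, opposite in sign to the excess among the lower calls. Without young replicate 2 camera called 2 classes, promoter-TSS and exon, both upward (adjusted p = 0.029 each).

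**Figure D4:**
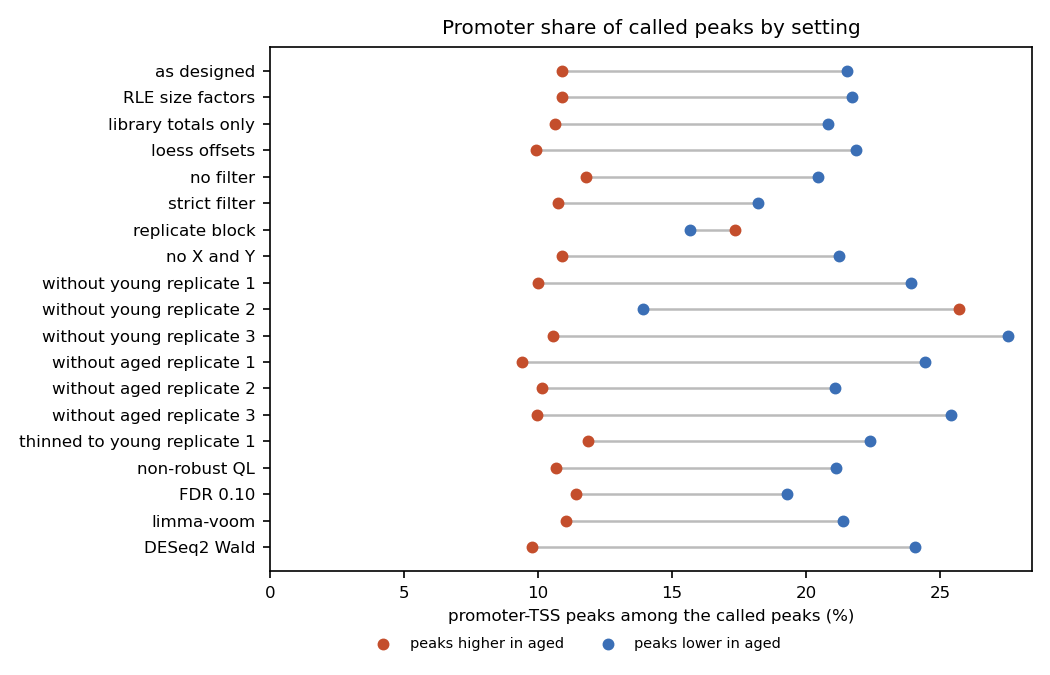
Promoter-TSS peaks as a percentage of the called peaks that rose (orange) and fell (blue) in aged, by setting of the aged against young test. The lower peaks held the larger share as designed (21.6% against 10.9%) and in the other settings except without young replicate 2 (13.9% against 25.7%) and with the replicate block (15.7% against 17.4%).

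The series title names inflammation and stem cells, and at promoters no list of inflammatory, antigen presentation or stem cell genes passed a test as a group. Interferon response promoters, which serve antiviral defence, had a median log2 fold change of 0.03 over 29 genes. NF-kB and inflammation promoters were at 0.04 over 23 and MHC class I and antigen processing at 0.00 over 10. MHC class II promoters were at -0.06, but over only 2 of the 10 list genes, too few to judge that list. Of the interferon genes with the smallest p, the transcription factors Irf7 and Irf9 were at 0.28 and 0.72 and Mx2 at -0.72. Of the NF-kB genes, the chemokine Cxcl1 was at 0.29, the siderophore-binding Lcn2 at 0.56 and the kinase Ripk2 at 0.13, which edgeR called higher only without young replicate 2 (log2 0.28, adjusted p = 0.0447, range over the processing alternatives 0.0447 to 0.9998). AP-1 and immediate early promoters had a median of -0.04 over 10 genes (Egr1 0.14, Fosb -0.18), antimicrobial lectins and peptides -0.07 over 8 (Reg3g -0.19), and senescence and p53 response -0.06 over 9 (Cdkn2b 0.24, Igfbp7 -0.44). Of 231 list genes with a tested promoter peak, edgeR called 0. Camera called 0 of the 22 lists with a preset or an estimated correlation (smallest adjusted p = 0.688), and 0 had an unadjusted p under 0.05.

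Camera called none of the cell-type and pathway lists at promoters either, while the tuft list passed the mixed fry test, which asks for changes in either direction (adjusted p = 0.0013). Intestinal stem cell promoters had a median of 0.02 over 14 genes (Olfm4 -0.30, Igfbp4 0.26), Wnt and Notch pathway 0.04 over 14 (Wnt3 -0.38, Tcf7 0.23), proliferation 0.02 over 10 and regenerative and fetal-like epithelium 0.00 over 7. Enterocyte promoters, at genes of nutrient uptake and lipid export, had the highest median, 0.15 over 14 genes of which 12 were positive (Slc15a1 0.41, Mttp -0.37; camera, adjusted p = 0.688). Goblet promoters were at -0.01 over 9 genes, Paneth -0.10 over 5, enteroendocrine 0.04 over 14, tuft 0.12 over 9 (Trpm5 0.49, Alox5 -0.51), epithelial identity transcription factors 0.04 over 15 (Pdx1 0.25) and distal intestine and colon -0.06 over 8 (camera, adjusted p = 0.688). Of the lists for other cell types, immune cells had 2 tested promoters (median -0.52), stromal cells 6 (0.10) and endothelial and neural cells 3 (0.02). Housekeeping promoters were at 0.07 over 11 genes. Median, mean and camera direction differed in sign for 10 of these lists. Camera gave down beside a positive median and mean for interferon response, stem cell, proliferation and regenerative genes, and beside a positive median and negative mean for MHC class I, enteroendocrine, stromal and endothelial and neural genes. Goblet genes had a negative median, a positive mean and down, and tuft genes a positive median, a negative mean and up. Adjusted over the list alone, 2 promoters passed, that of Hoxd10, a distal gut transcription factor (log2 -1.28, adjusted p = 0.013, 0.0997 over all peaks, 0.0391 with the replicate block, range 0.0391 to 0.4615), and that of the endothelial receptor Kdr (-0.65, 0.014, 0.187 over all peaks).

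**Figure D5:**
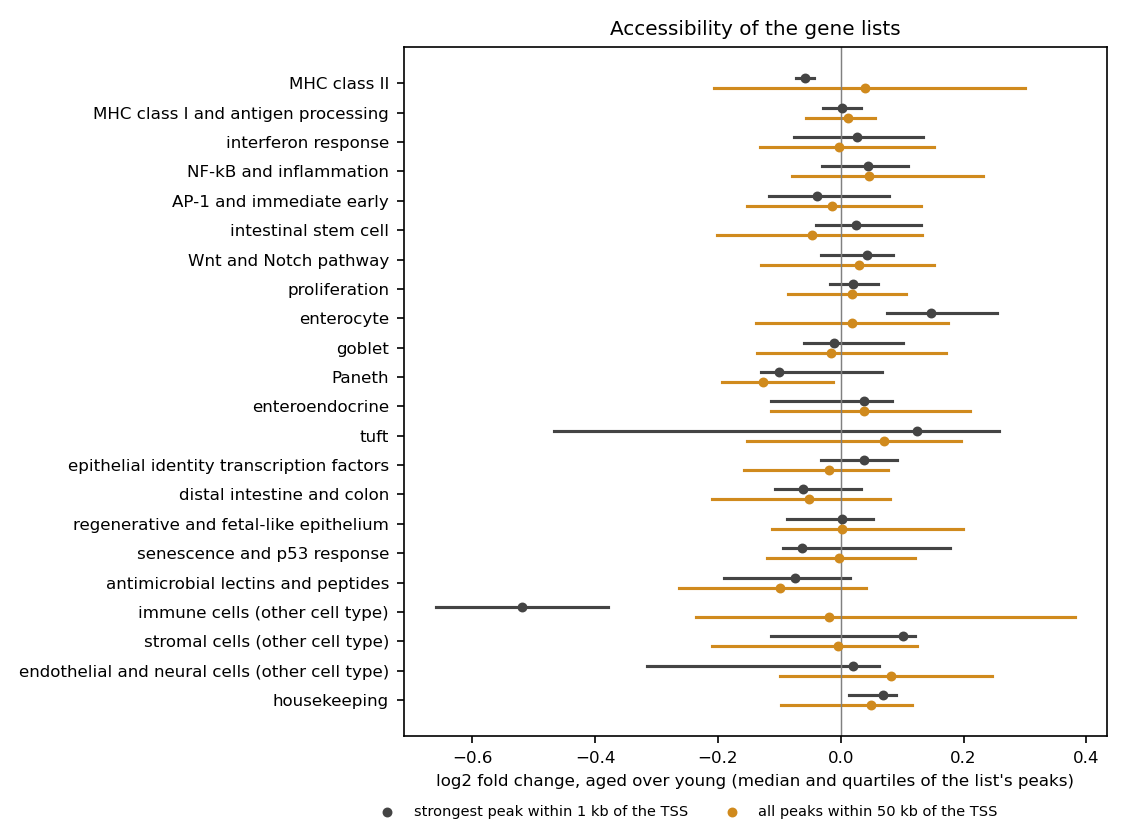
Log2 fold change, aged over young, of each gene list as the median (points) and quartiles (lines) of its peaks, for the strongest peak within 1 kb of the TSS (dark) and all peaks within 50 kb (yellow). Medians at promoters ran from -0.52 (immune cells, 2 genes) to 0.15 (enterocyte), and within 50 kb from -0.13 to 0.08.

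Within 50 kb of the TSS, single peaks of list genes changed, and no list passed a test for a shift in one direction. A peak in intron 4 of Cdk6, a cell-cycle kinase (chromosome 5, 3432819 to 3433739), went from 4.48 ± 0.778 to 11.4 ± 0.788 CPM (SD, n = 3; log2 1.38, edgeR adjusted p = 6.4e-07). An intron 4 peak of Usp18, which restrains interferon signalling (chromosome 6, 121255765 to 121256222), rose by 1.04 and an intron 2 peak of the calcium-binding S100b, from the list of endothelial and neural cells, by 0.95. A peak 7.19 kb from Onecut2, an epithelial transcription factor (chromosome 18, 64332722 to 64333622), went from 6.76 ± 1.77 to 2.38 ± 0.149 CPM (log2 -1.55, adjusted p = 1.8e-06), and one in intron 5 of the stem cell receptor gene Tnfrsf19 fell by 1.25. These 5 calls were kept with any 1 library left out. In all, edgeR called 12 of 1739 peaks at 325 list genes, a smaller share than the 1.13% called over all tested peaks. Of the 12, 8 were higher and 4 lower. Among the others were higher peaks near Apob (log2 1.19), Ciita (0.63), Relb (0.70) and Batf (1.19) and lower ones near Slc2a5 (-0.77) and Treh (-1.68). The Treh peak is annotated as a promoter of Treh but lies 10.9 kb from the TSS used for distances, so it was outside the promoter test.

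The peak 16 kb from Ciita, the master regulator of MHC class II genes (chromosome 16, 10471865 to 10472410), went from 7.33 ± 1.25 to 11.6 ± 0.740 CPM (SD, n = 3; edgeR adjusted p = 0.014). Its call was lost without young replicates 1 (0.0775) and 2 (0.0548) and aged replicate 1 (0.0966, range over the processing alternatives 4.4e-04 to 0.0966). The call near Relb, an NF-kB subunit, was lost without young replicate 3 (0.108) and aged replicates 1 (0.0789) and 3 (0.140, range 0.0011 to 0.140). That near Batf, an AP-1 factor, was lost without young replicates 1 to 3 (0.117, 0.0868 and 0.117) and aged replicates 2 (0.228) and 3 (0.171, range 0.0027 to 0.247). Of the enterocyte genes, the call of the fructose transporter Slc2a5 was lost without young replicate 3 (0.113) and aged replicates 1 (0.0555) and 3 (0.0551, range 2.6e-05 to 0.113). The call near the trehalase gene Treh was lost without young replicates 1 (0.0552) and 3 (0.0662, range 1.2e-04 to 0.0662), and that near the apolipoprotein gene Apob without aged replicate 3 (0.0576, range 8.4e-04 to 0.558). Adjusted over the list alone, 14 peaks passed, these 12 and those of Slc2a5 in its TTS (log2 -0.52, adjusted p = 0.049, 0.093 over all peaks, 0.0074 with the replicate block, range 0.0074 to 0.445) and of H2-Ab1, an MHC class II chain, in exon 2 (-0.63, 0.038, 0.130 over all peaks, 0.0125 with the replicate block). Without aged replicate 3 the H2-Ab1 peak was called over all peaks (log2 -0.90, edgeR adjusted p = 0.037, range 0.0125 to 0.459).

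As groups within 50 kb, camera called 0 of the 22 lists with a preset correlation (smallest adjusted p = 0.614) or an estimated one. At each setting 1 list had an unadjusted p under 0.05, antimicrobial lectins and peptides, downward, with the preset one (adjusted p = 0.614, median log2 -0.10 over 45 peaks) and NF-kB and inflammation, upward, with the estimated one (adjusted p = 0.815). Neither list was under 0.05 at the other setting. Inflammatory and antigen presentation lists had medians of 0.05 (NF-kB and inflammation, 160 peaks), -0.004 (interferon response, 159), -0.01 (AP-1, 80), 0.04 (MHC class II, 31) and 0.01 (MHC class I, 30). Stem cell peaks had a median of -0.05 over 186, Wnt and Notch 0.03 over 145, proliferation 0.02 over 63, regenerative 0.003 over 63 and senescence -0.002 over 53. Differentiated lineages lay at 0.02 (enterocyte, 168), -0.02 (goblet, 84), -0.13 (Paneth, 21), 0.04 (enteroendocrine, 77) and 0.07 (tuft, 51), epithelial transcription factors at -0.02 (111) and distal intestine and colon at -0.05 (49). Immune cells lay at -0.02 (22), stromal cells at -0.01 (33), endothelial and neural cells at 0.08 (41) and housekeeping genes at 0.05 (69). The mean had the opposite sign to the median for interferon response, AP-1, goblet, senescence, immune and stromal genes, of which camera gave up for all but AP-1, and for MHC class I and housekeeping genes, for which camera gave up. The directional fry test called 0 lists at either level. The mixed fry test called 1 list at promoters, tuft (adjusted p = 0.0013), and 4 within 50 kb, stem cell (0.015), tuft (0.015), MHC class II (0.018) and housekeeping (0.018). Of the peaks of the tuft and housekeeping lists none was called, so single members of these lists cannot be named.

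Of the 10 genes fixed by name, none was called at its promoter. The stem cell marker Lgr5 was at 34.3 ± 3.87 CPM in young and 33.4 ± 1.76 in aged (SD, n = 3; log2 -0.02), and Olfm4, another, at 10.96 ± 0.706 and 8.91 ± 0.436 CPM (log2 -0.30, edgeR adjusted p = 0.423). The senescence gene Cdkn2a was at 5.12 ± 1.36 and 6.08 ± 0.481 CPM (log2 0.18). H2-Aa was at log2 -0.09 and Cd74, the MHC class II invariant chain, at -0.03. H2-Ab1, H2-Eb1, Ciita and Irf1 had no tested peak within 1 kb of the TSS. By edgeR 5 of the 6 tested genes had an unadjusted p above 0.05, and Olfm4 had 0.028.

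Few peaks followed the passage of the culture, which each age shared with the replicate number. With each passage, a peak in a TTS of Ap5s1, a subunit of an adaptor complex of endosomes, rose by log2 0.41, and so did an intronic peak with the noncoding AU016765 as its nearest TSS, 59.3 kb away, by 0.39. Intronic peaks 31 kb from Gemin6, a part of the SMN complex, and 24.4 kb from the antisense transcript Gm7580 changed by log2 -0.96 and -0.79. The last 3 lie inside other genes. These were the 4 of 132055 peaks that edgeR called (adjusted p = 0.029, 0.049, 0.029 and 0.028), 6958 had an unadjusted p under 0.05, and DESeq2 called 0. The peaks are named below by these genes, and none of the 4 calls held with every library left out in turn. All were lost without young replicate 1 (Ap5s1 0.9999, AU016765 0.9999, Gemin6 0.553, Gm7580 0.415) and aged replicate 3 (0.0647, 0.912, 0.247 and 0.358), and some without young replicate 3 (Ap5s1 0.125, AU016765 0.105, Gm7580 0.286), aged replicate 1 (Ap5s1 0.0715, Gemin6 0.195) and aged replicate 2 (AU016765 0.0547), with a range over the processing alternatives of 2.4e-04 to 0.9999 for the 4 peaks. The number of calls was 0 without young replicate 1, 53 without young replicate 2, 8 without young replicate 3 and 20 without aged replicate 1.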

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

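The age by passage interaction and the tests of its causes were chosen only after the data were seen. Near Bmf, a pro-apoptotic BH3-only protein, and inside H2-Eb1, an MHC class II chain, the trend with passage differed between aged and young libraries. Passage was shared with the replicate number and the culture code of the titles, so a passage effect cannot be told apart from a difference between cultures. At the intergenic peak 9.36 kb from the Bmf TSS (chromosome 2, 118554343 to 118555012), young libraries had 31.6, 9.57 and 5.17 CPM at passages 4, 3 and 2 and aged libraries 17.6, 18.4 and 22.4 CPM (difference in log2 slope per passage, aged minus young, -1.51; edgeR interaction test, adjusted p = 7.7e-06). At the peak in exon 2 of H2-Eb1 (chromosome 17, 34309675 to 34310046), young libraries had 7.02, 7.72 and 8.39 CPM and aged libraries 5.64, 2.31 and 0.311 CPM, the last from 8 counts (difference in slope 1.94; adjusted p = 7.6e-04). These were the 2 of 132055 peaks called, with 3230 at an unadjusted p under 0.05. The Bmf call held in 7 of 7 alternatives (adjusted p from 6.5e-15 to 3.2e-05), while the H2-Eb1 call held in 6 and was lost when all libraries were thinned to young replicate 1 (difference in slope 1.64, adjusted p = 0.678, range 5.1e-09 to 0.678). Each rests on 1 library per age and passage, and fits with a library left out were not run for it. The highest young value at Bmf came from replicate 1, the shallowest library.

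The low value of H2-Eb1 in aged replicate 3 did not come from shallow sequencing, since that library had the highest total, 26093521 counts. Nor was a stretch that holds the neighbouring peaks lost: of the 4 nearest tested peaks, the lowest had a log2 ratio of aged replicate 3 to the young mean of -0.8648, against -4.63 at the H2-Eb1 peak. A sequence difference within the peak in some of the cultures, which could keep reads from mapping, and a change of H2-Eb1 chromatin in the aged cultures both stay open and untested.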

How the results depend on the processing

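The thinned libraries, the comparison of promoter shares and the interaction test were chosen only after the data were seen. The number of called peaks was 1481 with library totals alone, 1495 with RLE factors (1483 shared), 1539 with loess offsets (1456 shared), 1779 without a filter, 1056 with the strict filter, 1461 without X and Y, 1467 with non-robust dispersions, 1273 with limma-voom and 2157 at an adjusted p under 0.1. It moved by over 1.5 times with DESeq2 (901, 502 higher and 399 lower, with 12803 adjusted p-values not given), and when all libraries were thinned to young replicate 1 (681, 413 higher and 268 lower, 615 shared), where fewer peaks and counts were tested, so depth limits the count. The strict filter left 395 lower peaks. With 1 library left out the count ran from 830 to 1902, the higher peaks from 452 to 1061 and the lower from 378 to 841. The difference in promoter-TSS share of called peaks, lower minus higher, percentage points, was 10.7, and 7.49 to 14.3 under the other scalings, filters and tests, and with 1 library left out it ran from -11.8 (without young replicate 2) to 16.95. Camera called 0 to 2 classes with 1 library left out and 1 with the strict filter (cause not tested), and 0 of the 22 lists at promoters and within 50 kb under every alternative run. Passage calls were 32 without a filter, 0 with the strict filter, 0 with DESeq2 and 0 to 53 with 1 library left out, and the cause was not tested. The interaction gave 5 calls without a filter and 1, Bmf, with thinned libraries. The aged minus young difference in the share of the top 1% of peaks was 0.192 percentage points, and -0.0392 to 0.401 with 1 library left out, and those of total counts, promoter share and chromosome X kept their sign.

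Of values under the alternatives, 337 of 341 for the named peaks, 188 of 212 for the called list peaks, 2105 of 2537 for the called coding promoters and 30 of 56 for the passage peaks kept direction and side of the threshold, and none reversed. With the replicate block edgeR called 3523 peaks (1930 higher, 1593 lower), among them all 1491, and the difference in promoter share was -1.66 points (Fisher's exact p = 0.188). The block also called the list peaks of Slc2a5, H2-Ab1 and Hoxd10 (adjusted p = 0.0074, 0.0125 and 0.0391), and changed no other call among the results refitted. The motif sets and the GC corrections were not run, because no genome sequence was used here.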

Other observations

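The runs of neighbouring calls, the chromosome 12 copies and the tests below were chosen only after the results were seen, except the fits with loess offsets and without young replicate 1 and the splits of the libraries. Beyond the Tiam1 and Hoxd loci, calls of one direction lay side by side. Of 40 called peaks of such loci that were refitted with each library left out, 28 kept their calls in all 6 fits, and each peak given here kept its call in all 6. On chromosome 11 (43836234 to 44002388), 5 peaks nearest to Gm12153, beside the adrenergic receptor gene Adra1b, rose by log2 0.75 to 2.85. On chromosome 12 (85631096 to 85647930), peaks nearest to Jdp2, an AP-1 factor, rose by 1.75 and 1.51, and on chromosome 15 (74935318 to 74958093), beside Ly6e, peaks nearest to Gm6610 and Gm29126 rose by 2.66 and 2.44. Around Wnt5a, a noncanonical Wnt ligand (chromosome 14, 28417008 to 28501877), peaks fell, with log2 fold changes of -1.52, -1.08 and -0.80. Peaks of Gpc3 (chromosome X, 52533149 to 52643750) had -1.87, -2.46 and -1.70, and the Tiam1 peaks were followed by peaks nearest to Sod1, the cytosolic superoxide dismutase (chromosome 16, 90073637 to 90105392), with -1.73 and -1.24. In a stretch of chromosome 12 with many near-identical gene copies (18514264 to 24097532), 14 of 83 tested peaks were called, 12 of them lower, with -3.36 at 9030624G23Rik. Reads can be shared between such copies. The 83 also include the peaks of genes such as Asap2, Itgb1bp1 and Ywhaq in the middle of the stretch, none of which was called lower.

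Called peaks neighboured calls of the same sign more often than independent placing gives. Of 303 neighbouring called pairs within 100 kb, 272 had one sign, against a median of 88 and at most 126 such pairs in 1000 random placings of the calls among tested peaks. Of the 19 runs of 4 or more calls, 16 had one direction and 3 were mixed. A copy-number change of a whole region, acting alone, would move all its peaks alike. In 14 of the 19 runs folds were unequal beyond their errors (Cochran Q over all tested peaks of a run, adjusted). Calls are picked for large folds, so uncalled peaks between them make unequal folds likely, as around Btn2a2 (6 of 30 called). Where most tested peaks were called, as in Tiam1 (6 of 7, log2 -1.04 to -5.39), unequal folds argue against such a change as the only cause. The 14 include the 3 mixed runs, whose opposite signs fixed unequal folds in advance. A change of part of a run, or one beside other changes, stays open. For the other 5, nearest to Gm5670, Gm6746, Sod1, Olfr109 and Arglu1, a copy-number change cannot be told apart from other causes, because equal folds also arise otherwise. Shared regulation of a domain and a sequence or structural difference between the mice of the 2 ages could each give such runs, and neither was tested.

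The larger promoter share among lower than among higher calls (10.7 points) did not hold with the replicate block (-1.66 points, Fisher's exact p = 0.188), so over all calls it depended on the fit. In fits without the block it did not come from the low depth of young replicate 1, without which it was 13.93 points, nor from a scaling that changes with abundance, since it was 11.93 points with loess offsets. Leaving out young replicate 2 gave -11.82 points, so the split in the fits without the block may rest on that library, which had the highest promoter share of the young (31.56%). Its reversal came with 206 added higher promoter calls of small size, while 92 of the 145 lower promoter calls were kept. The difference among calls of 2-fold or more fell from 17.6 points in all libraries to 9.21 points without young replicate 2, and to 14.2 points with the block. A 2-fold cut leaves out most of the small added calls, so the direction kept there decides little. A change of weakly open promoters with age stays open.

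Promoter-TSS peaks as a whole were not lower than other peaks in the aged libraries after TMM scaling. The median log2 fold change of all tested promoter-TSS peaks was 0.0261, against -1.41 for the lower called ones. Calls are picked for large folds, so that gap was fixed in advance and excludes no source of the lower calls. A change shared by all peaks would be removed by the scaling. Because weakly open promoters were called lower more often (72 of the 2134 least open protein-coding genes with a tested promoter, 0 of the 2134 most open), gene families were tested within 5 strata of openness. Homeobox genes, noticed among the lower calls, made up 6 of 122 against 96 of 10548 other genes (Alx1, Hoxc10, Hoxd1, Hoxd11, Hoxd9 and Meis1; exact Mantel-Haenszel odds ratio 2.423, 95% interval 0.842 to 5.71, p = 0.049, BH-adjusted 0.221). Imprinted genes, of which Peg3 and Grb10 were lower, gave an odds ratio of 4.982 (0.542 to 22.1, adjusted p = 0.221), and Zfp-named zinc finger genes 2.197 (0.431 to 6.98, adjusted p = 0.341). None of the 3 hypotheses passed the test, and the intervals leave each open.

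The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1491 called peaks and the highest other split 3, so 1 of 10 splits gave as many (the 3 other splits that part every same-numbered pair called 0). For the promoter share difference (10.7 points) 1 of 10 splits gave as large a value (highest other 0), which decides nothing, because the other splits called 0 to 3 peaks, too few for a share. For classes and for lists at promoters and within 50 kb the real count was 0, so 10 of 10 splits gave as many, and the highest other counts were 1, 2 and 4.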
